A study of Homo sapiens with 73 samples.

How the data were processed

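Total RNA came from sections of formalin-fixed, paraffin-embedded tumour biopsies, per the labels. Fragmented RNA was converted to cDNA by random priming, coding regions were captured with probes (RNA exome sequencing), and the libraries were sequenced on an Illumina instrument. Formalin fixation breaks RNA, and capture measures only what the probes cover. The deposited values are a non-negative signal, normalized counts per gene, scaled by the authors. Their totals per library had a median of 2.24e+07 and ran from 1.90e+07 to 5.19e+07. Salmon, edgeR and the build hg19 are named in the submitters' processing notes, without versions, roles or order. Response, subtype calls and raw reads were not used here.

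The table holds 12299 genes by Ensembl identifier and symbol, of which 12212 identifiers were found in a human gene name table and 12158 had the same symbol. The reference genome at hand was of another build, so no coordinates are given. Every listed gene reaches at least 340.4 normalized counts in some library, so genes low everywhere are not analysed here. Many immune genes are not listed either, and the reason was not tested. Low values lie at regular steps that are offset from 0. Exact zeros occur in 49 libraries, and in the other 24 no gene is at 0. Whole reads could therefore not be recovered, and no count model was run. The step size was taken as the value of 1 read and gave an estimated depth of 6.26e+06 to 3.42e+07 reads. In 3 libraries, 2 from Day0 and 1 from Day15, 1 read was worth 2.70 to 6.11 normalized counts, against 0.627 to 1.59 in the others. These high-step libraries were set apart by the value of 1 read, over 2, and not by depth, since 1 of them had 1.80e+07 estimated reads and the lowest of the others 1.27e+07.

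Groups and patients were taken from the sample labels. The pairing comes from the labels, since libraries of 1 patient share a number. The 36 pairs (72 libraries) entered the tests, and the 1 Day15 library without a partner entered only the fits without the block or with patient as a random effect. Deviations from the group means correlated at a median r of 0.564 across genes within patients (-0.148 to 0.882, over 0.1 in 34 of 36 pairs) and -0.017 between patients, and 52 of 72 libraries correlated best with their own patient. A check for mixed-up samples by sex-linked genes left 2 of 36 pairs not matching at the threshold first used, the middle of the range of values. A threshold in the widest gap between values, chosen after that count was seen, left 0 not matching. The check thus depends on its threshold, and no pair was left out on its account.

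Genes were tested with limma 3.58.1 in R 4.3.3 on log2(value + 1) with the patient as a block, trended and robust empirical Bayes moderation and Benjamini-Hochberg adjustment, two-sided at 0.05. A change is on that scale and understates the change of low genes. The patient block was the main design because the series describes repeated biopsies of the same patients. The 7 Y-linked genes were left out, leaving 12292. The filter on the mean, at 1, removed no gene, since the lowest gene mean is 6.44. Data were simulated from the patient means and residual SD of each gene, with independent normal noise (12292 genes, 50 changed per size). There limma recovered 24% of genes changed by 0.25 on the log2 scale, 64% at 0.5, 86% at 1 and 98% at 2. It made 8 false calls among 12092 unchanged genes. Genes that move together and outlying libraries were not simulated, so these rates need not hold for the real libraries.

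Before the data were examined, 47 gene lists were fixed for pathways and cell types, and 40 had at least 3 measured genes. A list score is the mean log2 value of its measured genes. Its change was tested by flipping the sign of the paired differences 100000 times, two-sided, with Benjamini-Hochberg adjustment over 40 lists, and intervals are 95% t intervals. Camera with a preset correlation of 0.01, camera with an estimated correlation and fry were run beside it. Camera compares a list with other genes, and fry tests whether its genes move one way on balance. Correlations carry permutation p-values with 100000 resamples. Scores and permutations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.

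Genes named in the text follow a rule fixed in advance. It takes up to 12 genes per direction past the threshold with the same sign in at least 60% of pairs. Because fewer than 5 genes passed, the 10 with the smallest unadjusted p are given as values. To these the rule adds up to 4 members per list past the threshold, or else the 2 with the smallest p, and TGFB1, TGFBR1, TGFBR2, SMAD7, CD8A, GZMB, FOXP3, EPCAM, COL1A1 and MKI67. Values of 2 genes that the rule or the small lists would name are not reported here. The remaining p53 targets, members of lists too small to score and 3 genes of a second p53 list were named beyond the rule, after their values were seen.

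Other settings tried were other pseudocounts (0.5 and 5), no filter or a mean filter at 5, quantile and upper-quartile scaling, no block, patient as a random effect, library quality weights, a signed-rank test, the epithelial score as covariate, plain empirical Bayes moderation and z-scores. Settings chosen after seeing the data left out the pairs with a high-step library (33 pairs remained) or the 1 pair farthest from a list's median change, dropped the block over the 72 paired libraries alone, kept genes with a median of at least 50 (11657 genes), or took the mean change given the epithelial change.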

Results

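RNA was measured in tumour biopsies of patients with rectal cancer who took part in a trial of galunisertib with chemoradiation. Galunisertib is a small-molecule inhibitor of the kinase of the TGF-beta type I receptor. Each patient gave a biopsy at baseline (Day0) and another after 2 weeks of galunisertib (Day15), so the design asks what changed in the tumour between the biopsies. The labels name galunisertib and chemoradiation without dates, so whether chemoradiation had begun before Day15 is not known here. The 73 libraries comprised 36 from Day0 and 37 from Day15, and 36 patients had both. Every library carried the same treatment label, so no untreated patients stood beside them, and tumour response and subtype calls were not analysed here. The table listed 12299 genes, and the estimated depth ran from 6.26e+06 to 3.42e+07 reads per library with a median of 2.38e+07. Depth, detection and the share of the 50 highest genes did not separate the days (smallest adjusted p = 0.773, permutation test over 36 pairs).

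Targets of p53, the transcription factor activated by DNA damage, were higher in the Day15 biopsies. The score of 14 p53 targets rose by 0.34 ± 0.49 on the log2 scale (SD, n = 36 patients), which is 1.26-fold, with a 95% interval of 0.17 to 0.50. The score was higher at Day15 in 27 of 36 patients and lower in 9. Of the 14 genes, 13 had a higher mean at Day15, and 7 rose when adjusted over the list alone. These were CDKN1A, the cell cycle inhibitor p21; MDM2, the ubiquitin ligase that degrades p53; BBC3 and BAX, which promote apoptosis; GDF15, a secreted stress cytokine; FDXR, a mitochondrial ferredoxin reductase; and ZMAT3, an RNA-binding protein.

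Among these 7 genes the change was 0.74 ± 0.24 (SE) for GDF15 and 0.67 ± 0.14 for FDXR. CDKN1A rose by 0.57 ± 0.14, BBC3 by 0.52 ± 0.13, MDM2 by 0.44 ± 0.13, BAX by 0.34 ± 0.09 and ZMAT3 by 0.25 ± 0.10. Their adjusted p over the list alone ran from 0.000588 for FDXR to 0.0237 for ZMAT3. The values of FAS (0.30 ± 0.15), PHLDA3 (0.48 ± 0.24) and XPC (0.14 ± 0.06) did not pass over the list alone. SESN1, TNFRSF10B, SESN2 and RRM2B had values of 0.03, 0.07, 0.17 and -0.00. None of the 14 genes passed in limma when adjusted over all genes, where 8 of them had an unadjusted p under 0.05.

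The permutation test of the p53 score gave p = 0.00016 and an adjusted p of 0.0064 over 40 lists. In limma, camera with a preset correlation gave an adjusted p of 1.02e-11 for the list, and camera gave adjusted p = 0.04 with an estimated correlation. That correlation was estimated at 0.285, well above the preset 0.01, so the preset overstates the evidence. The adjusted p of fry was 0.0129. Without the patient block, over the same 72 libraries, a setting chosen after seeing the data, the score had an adjusted p of 0.0856 and fry gave an adjusted p of 0.144, so the calls of the score test and of fry rest on the pairing of biopsies within patients. Camera without the block kept the call (adjusted p = 3.57e-12, and adjusted p = 0.0223 with an estimated correlation). With all 73 libraries and no block, the change was 0.33 with an adjusted p of 0.0924.

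**Figure D1:**
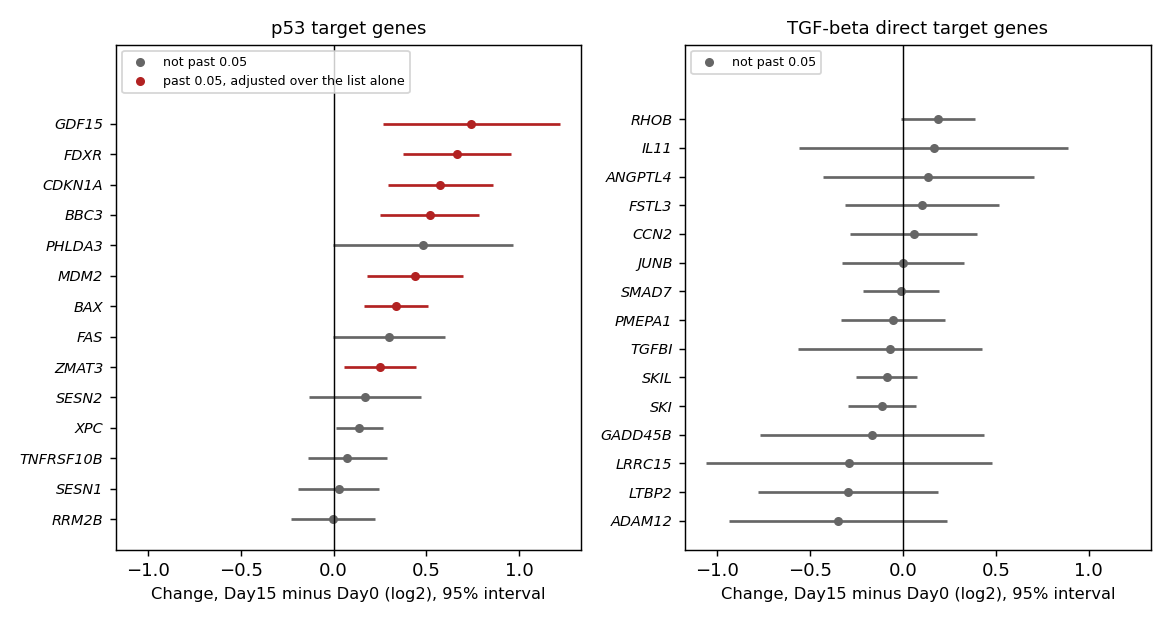
Change of each p53 target (left) and of 15 of the 16 direct TGF-beta targets (right) from Day0 to Day15 on the log2 scale, with points for the mean over 36 patients and lines for the 95% interval. Red marks the 7 p53 targets that passed when adjusted over the list alone, and no TGF-beta target passed.

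Direct targets of TGF-beta signalling, the pathway that galunisertib inhibits, did not separate the days. The score of 16 targets differed by -0.02 ± 0.85 (SD, n = 36), with a 95% interval of -0.31 to 0.27, and 19 patients were higher and 17 lower (adjusted p = 0.969, permutation test). RHOB, a small GTPase, had a value of 0.19 ± 0.10 (SE), and SMAD7, the feedback inhibitor of the pathway, had -0.01 ± 0.10. The 19-gene fibroblast response to TGF-beta differed by -0.05 ± 0.75 (SD), where RFLNB had -0.31 ± 0.16 (SE) and ADAM12 had -0.35 ± 0.29.

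The 20 components of the pathway, which include ligands, receptors and SMADs, differed by -0.06 ± 0.36 (SD). TGFB1 itself had a value of -0.49 ± 0.23 (SE) and LTBP1, which holds the latent ligand in the matrix, had -0.22 ± 0.12. The receptors TGFBR1 and TGFBR2 had -0.06 ± 0.09 and -0.10 ± 0.08. The 11 genes of BMP signalling and its ID targets differed by -0.05 ± 0.56 (SD), with values of 0.21 for ID1 and 0.16 for BMP2. These 4 lists had an adjusted p of 0.969 each. None of their members passed in limma over all genes or over the list alone, and 1 of the pathway components, TGFB1, had an unadjusted p under 0.05.

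Matrix and stromal genes varied widely between patients. The score of 28 fibroblast and matrix genes differed by -0.21 ± 1.90 (SD, n = 36), and single patients ranged from -4.15 to 3.83. Its members VCAN and SFRP4 had values of -0.56 ± 0.22 (SE) and -0.86 ± 0.41, and the collagen gene COL1A1 had -0.09 ± 0.35. The score of resident fibroblasts differed by -0.10 ± 1.40 (SD), with FBLN1 at -0.45 and APOD at 0.21. Smooth muscle differed by -0.05 ± 1.41, with SMTN at 0.10 and DES at 0.30, and pericytes by 0.02 ± 1.10, with ABCC9 at -0.14 and CSPG4 at 0.19. Blood endothelium differed by 0.18 ± 1.52, with VWF at 0.38 and ESAM at -0.18, or by 0.05 without the 1 pair farthest from the median, and lymphatic endothelium by -0.07 ± 1.23, with PROX1 at 0.15 and PDPN at -0.19. The 4 mesenchymal genes ZEB1, ZEB2, SNAI1 and VIM differed by -0.27 ± 1.08, with ZEB2 at -0.50 and ZEB1 at -0.36, and by -0.11 without the 3 high-step libraries, in which 1 read was worth over 2 normalized counts, and their partners or -0.06 given the epithelial change. All of these had an adjusted p of 0.969 by permutation.

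Immune lists did not separate the days either, and many lymphocyte genes were not analysed here, CD8A and FOXP3 among them. Cytotoxic genes differed by -0.05 ± 0.55 (SD, n = 36), with KLRD1 at -0.21, CCL5 at -0.11 and GZMB, a cytotoxic granule protease, at 0.14. The interferon-gamma response differed by 0.01 ± 0.80, with TAP1 at 0.14 and GBP5 at -0.40, and the type I interferon response by -0.30 ± 1.22, with IFI44L at -0.73 and IFI44 at -0.44. B cell genes differed by -0.16 ± 1.74 (FCRL1 -0.56, CD22 -0.27), or by -0.03 without the 1 pair farthest from the median, and plasma cell genes by 0.09 ± 0.77 (FKBP11 0.11, SDC1 0.18). Macrophage genes differed by -0.14 ± 0.84 (FCGR3A -0.49, CD14 -0.45) and neutrophil genes by -0.38 ± 2.45 (S100A9 -0.53, MNDA -0.43). Without the 3 high-step libraries and their partners, the type I interferon score differed by -0.11 and the neutrophil score by 0.11. Inflammatory cytokines differed by 0.02 ± 1.88 (CCL20 0.39, CXCL3 0.30), or 0.39 without those pairs, and mast cell genes by -0.06 ± 1.34 (CPA3 -0.21, TPSB2 -0.08). Lists with fewer than 3 measured genes were not scored. Their members had values of -0.14 for CD3E and 0.12 for CD6 (T cells), -0.17 for IKZF2 and -0.16 for TNFRSF9 (regulatory T cells), 0.08 for CD274 and -0.09 for HAVCR2 (checkpoints), and -0.34 for CCR3 (eosinophils). L1CAM of enteric glia had -0.23, and PLIN4 and CIDEC of adipocytes had 0.17 and 0.48, while 0 genes of the dendritic cell list were measured.

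The epithelial score, which follows the share of tumour and other epithelium, differed by 0.19 ± 0.63 (SD, n = 36, p = 0.0584, adjusted p = 0.969). All 13 of its genes had a higher mean at Day15, among them CDX1 (0.30 ± 0.12, SE), ELF3 (0.23 ± 0.11) and EPCAM (0.26 ± 0.12), and none passed over the list alone (3 had an unadjusted p under 0.05 in limma). Without the 3 high-step libraries and their partners, a setting chosen after seeing the data, the score differed by 0.06. Differentiated cells differed by 0.07 ± 2.36 (SD) for mature colonocytes (CA4 0.67, AQP8 -0.56), 0.18 ± 1.91 for goblet cells (AGR2 0.31, SPDEF 0.41; 0.03 without the 1 pair farthest from the median), 0.47 ± 2.24 for enteroendocrine cells (GCG 0.58, SST 0.47) and -0.10 ± 0.64 for tuft cells (AVIL -0.29, PTGS1 -0.24). Squamous epithelium differed by -0.21 ± 2.06 (SPRR3 -0.56, KRT5 -0.58), where 1 pair set the sign and most of the spread, with 0.10 ± 0.89 over the other 35 pairs. Wnt and stem cell genes differed by -0.01 ± 1.03 (LEF1 -0.35, LGR5 -0.33) and regenerative epithelium by 0.05 ± 0.90 (IL33 0.39, KRT7 0.57).

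Cell cycle genes differed by 0.06 ± 1.16 (SD, n = 36), with TYMS, which makes thymidylate, at 0.44 ± 0.15 (SE), PCNA at 0.33 and MKI67 at -0.01. MYC and ribosome biogenesis genes differed by 0.14 ± 0.88 (PPAN 0.31, RRP9 0.21), hypoxia genes by 0.01 ± 0.68 (EGLN3 0.29, PDK1 -0.08) and immediate early genes by -0.07 ± 1.02 (ATF3 0.43, EGR3 -0.43). Blood RNA differed by -0.33 ± 1.98 (HBA1 -0.63, ALAS2 -0.72), and by -0.09 ± 1.38 without the 1 pair farthest from the median. Signs of RNA quality differed by -0.07 ± 0.97 for mitochondrial mRNAs (MT-CYB -0.13, MT-CO1 -0.10) and 0.07 ± 0.72 for ribosomal protein mRNAs (RPLP1 0.12, RPL13 0.15).

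Across the 40 lists, 1 score changed, and the 39 others had an adjusted p of 0.969. The small differences of these 39 were unstable, in 3 settings chosen after seeing the data. A ratio to a value near 0 moves easily, so the next counts partly reflect how small the differences were. Leaving out the 1 pair farthest from a list's median change moved 36 of the 39 by over 1.5 times or turned their sign, leaving out the 3 high-step libraries and their partners did so for 27 of 39, and adjusting for the epithelial change for 30 of 38. Of the 450 genes in those 39 lists, 13 had an unadjusted p under 0.05 in limma and 0 passed when adjusted over the list alone. Camera with a preset correlation placed 8 lists past an adjusted p of 0.05. Besides the p53 targets these were epithelial and MYC genes, with higher means at Day15, and CMS4, type I interferon, neutrophil, matrix and mesenchymal genes, with lower means. These 7 had adjusted p = 0.974 with an estimated correlation, which ran from 0.542 (mesenchymal genes) to 0.892 (neutrophil genes) against the preset 0.01. The preset thus treats their genes as far more independent than they were. Fry placed 1 list past the threshold, the p53 targets.

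**Figure D2:**
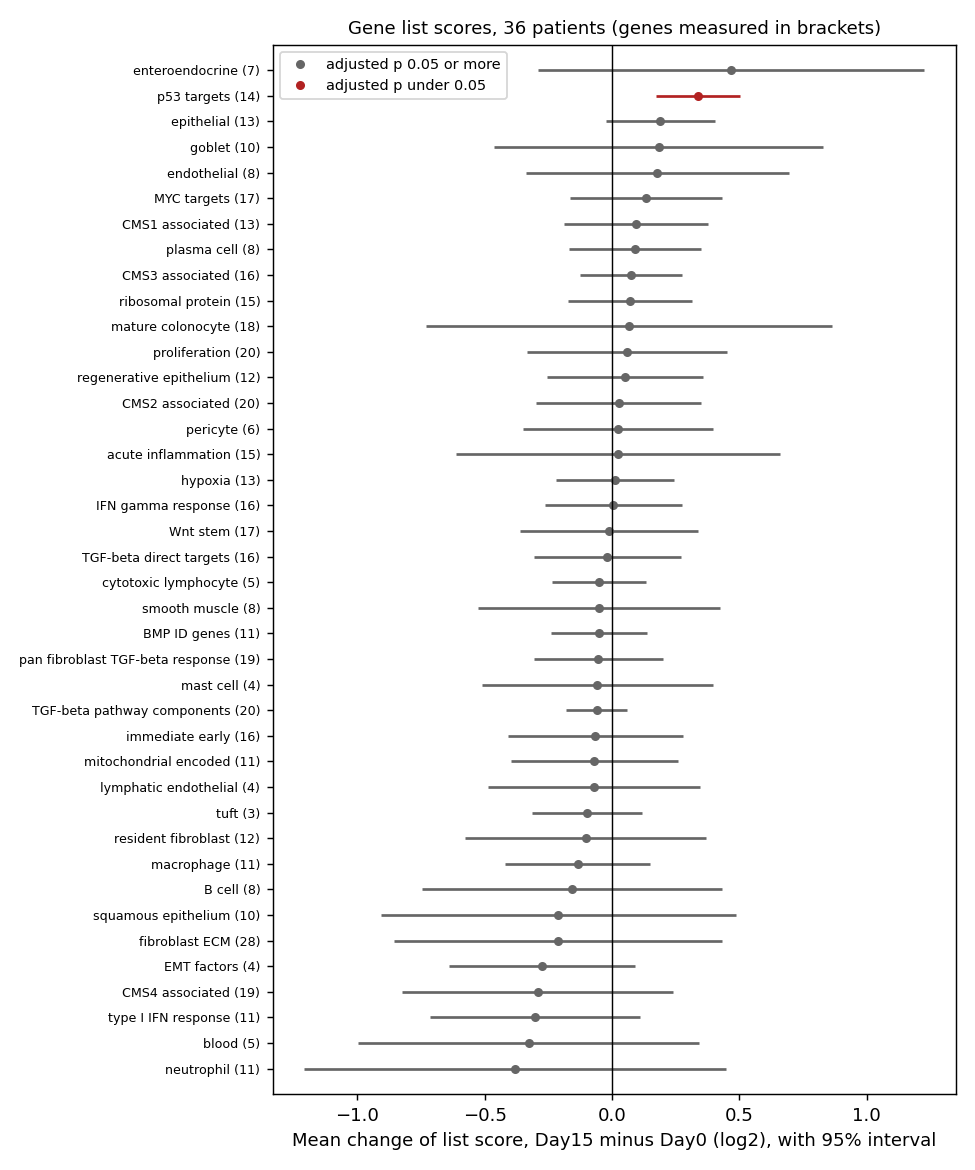
Mean change from Day0 to Day15 of each of 40 gene list scores on the log2 scale, with points for the mean over 36 patients and lines for the 95% interval. The p53 targets (0.34, interval 0.17 to 0.50) are in red, and the intervals of the 39 others include 0.

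Single genes gave 0 of 12292 past an adjusted p of 0.05 in limma with the patient block, and 625 at an unadjusted p under 0.05 (330 higher and 295 lower at Day15), which is 5.08% of the genes. The signed-rank test also gave 0, with 718 at an unadjusted p under 0.05, and patient as a random effect gave 0, with 719. Library quality weights in limma gave 5 genes, all higher at Day15, which were CDKN1A, DDB2, POLH, BBC3 and FHL2; FHL2 was named after its values were seen.

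The 10 genes with the smallest unadjusted p are given as values. DDB2 (ENSG00000134574), which recognises ultraviolet damage in DNA, had a value of 0.50 ± 0.10 (SE, n = 36), was higher in 29 patients and had an adjusted p of 0.111 in limma. POLH (ENSG00000170734), a translesion DNA polymerase, had 0.39 ± 0.08, also higher in 29 patients, with an adjusted p of 0.111. FDXR (ENSG00000161513) was higher in 30 patients, CDKN1A (ENSG00000124762) in 28, BAX (ENSG00000087088) in 27 and BBC3 (ENSG00000105327) in 26. TMEM238 (ENSG00000233493) had 0.37 ± 0.09, RPS27L (ENSG00000185088) had 0.34 ± 0.09, ZFPM1 (ENSG00000179588) had 0.25 ± 0.07 and PCMTD1 (ENSG00000168300) had -0.25 ± 0.07. Of these 10 genes, 9 had a higher mean at Day15 and 1 a lower one. The p53 list holds 4 of them. That list is short, so absence from it does not mean that a gene is no p53 target. Whether the others respond to p53 was not tested.

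Genes associated with the consensus molecular subtypes of colorectal cancer, CMS1 to CMS4, which the series title names, did not separate the days. The immune CMS1 genes differed by 0.10 ± 0.83 (SD, n = 36), with TFF2 at 0.41 and MUC5AC at 0.34. The Wnt and MYC CMS2 genes differed by 0.03 ± 0.96, with VAV3 at -0.08 and HNF4A at 0.08, and the metabolic CMS3 genes by 0.07 ± 0.59, with HADH at 0.21 and FBP1 at 0.18. The mesenchymal CMS4 genes differed by -0.29 ± 1.57, with SFRP4 and ZEB2 at -0.86 and -0.50. These lists are hand-written genes and not a subtype classifier, and 8 of the CMS4 genes are also on the matrix list.

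**Figure D3:**
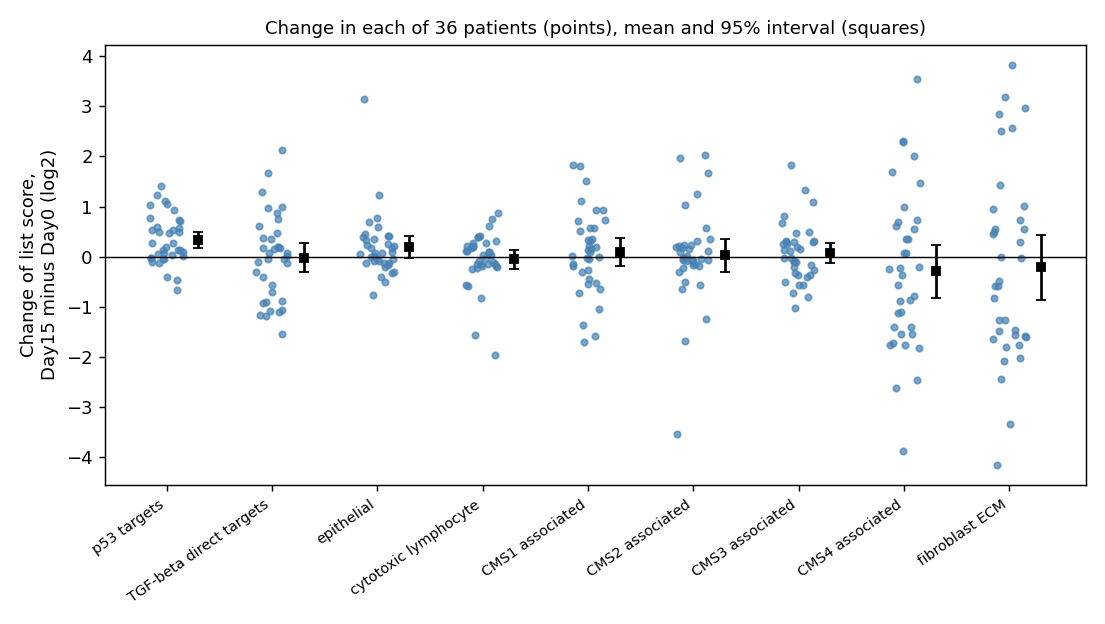
Change of 9 list scores from Day0 to Day15 on the log2 scale, with a point for each of 36 patients and squares with bars for the mean and its 95% interval. The matrix score ranges from -4.15 to 3.83 and the p53 score from -0.65 to 1.4.

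The order of patients held between biopsies for some of these scores. Across 36 patients the Day0 and Day15 scores correlated at r = 0.574 for CMS2 (adjusted p = 0.00261), 0.504 for CMS3 (adjusted p = 0.00534), 0.462 for CMS1 (adjusted p = 0.0108) and 0.529 for cytotoxic genes (adjusted p = 0.00534), by permutation over 9 lists. In the same order rho was 0.608, 0.517, 0.483 and 0.412, with adjusted p of 0.00135, 0.00648, 0.00945 and 0.0295. Without the 2 patients farthest from the median Day0 score, r was 0.559, 0.571, 0.526 and 0.451. The correlation of CMS4 genes was r = 0.145 (adjusted p = 0.472, with rho = 0.15), of matrix genes 0.139 (rho = 0.18), of direct TGF-beta targets 0.219 (rho = 0.194) and of the fibroblast response 0.227 (rho = 0.247), and these did not pass. Epithelial genes gave r = 0.09 (adjusted p = 0.615) and rho = 0.355 (adjusted p = 0.0616). Without the 2 farthest patients r was 0.187 for CMS4 genes, 0.155 for matrix genes, 0.096 for direct targets, 0.413 (p = 0.0154) for the fibroblast response and 0.392 (p = 0.0212) for epithelial genes, by permutation and unadjusted. Whether the correlations differ between lists was not tested.

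Changes of the TGF-beta targets went with changes of matrix genes within patients. Across 36 patients r was 0.793 (rho = 0.823, p = 1e-05, the smallest the permutations can give, adjusted p = 6e-05 over 6 relations), and 0.751 without the 2 patients farthest from the median. The 2 lists share 0 genes, but 4 of the direct targets are also on the fibroblast response list. Both scores may thus follow the share of stroma in a biopsy, which was not tested for this relation. The change of the interferon-gamma response correlated at r = 0.447 (p = 0.00666, adjusted p = 0.02) and rho = 0.511, with r = 0.43 without those patients. That of the epithelial score correlated at r = -0.378 (p = 0.0223, adjusted p = 0.0335) and rho = -0.441, with r = -0.421 without those patients. For the epithelial score r was -0.288 after quantile normalization and no longer passed (adjusted p = 0.134). Given the epithelial change, r was 0.771 for matrix genes and 0.327 for the interferon-gamma response. Pearson's r of the latter no longer passed (adjusted p = 0.087), while its rho of 0.386 did (adjusted p = 0.0353).

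Cell cycle genes gave r = 0.4 (p = 0.0155, adjusted p = 0.031) and rho = 0.259 (adjusted p = 0.167), and 0.328 (p = 0.0585) without the 2 farthest patients, where it no longer passed. Given the epithelial change r was 0.508 (adjusted p = 0.00438) and rho 0.402 (adjusted p = 0.0353), and r was 0.452 (p = 0.00675) without those patients. Cytotoxic genes gave r = 0.062 (p = 0.724, adjusted p = 0.724) and rho = -0.031. The 2 measured regulatory T cell genes gave r = 0.169 (p = 0.324, adjusted p = 0.389) and rho = 0.251.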

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

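The runs without the pairs holding a high-step library, without the pair farthest from the median change, without the block over paired libraries alone, with the median filter and given the epithelial change were chosen only after the results were seen. Genes past the threshold numbered 0 in limma (625 at an unadjusted p under 0.05) and in 14 of 15 alternatives, the signed-rank test included (718), and 5 with library quality weights, with 1362 at an unadjusted p under 0.05. The runs with no filter and with a mean filter at 5 are among the 14 but removed no gene, so they repeat the main fit and add no support. The unadjusted count was 338 with the epithelial covariate. The smallest adjusted p ran from 0.00155 to 1 over the alternatives. The p53 score kept its call in 7 of 9 alternatives, between 0.306 and 0.409, with the z-score on its own scale. Without the patient block its change was 0.33 over all 73 libraries and 0.337 (adjusted p = 0.0856) over the 72 paired ones, and 0 lists passed in either (1 list had passed with pairing), with 141 and 148 genes at an unadjusted p under 0.05. Removing the block and adding the library with no partner turned the sign of acute inflammation (-0.00), Wnt and stem cell genes (0.008) and MKI67 (0.022), none past the threshold by score, and these kept their sign over the 72 paired libraries, so the turns come from the added library. Without the block camera with the preset correlation gave 9 lists over 73 libraries, with macrophage genes added (adjusted p = 0.0462, but adjusted p = 0.936 with an estimated correlation), and 8 lists over 72. In both, fry lost the p53 targets (0.152 and 0.144 against 0.0129). With the block, camera with an estimated correlation gave 1 list and fry 1 list, against 8 with the preset correlation. The camera runs with the block differ only in that correlation. It was estimated at 0.285 for the p53 targets and at 0.542 to 0.892 for the lists that were lost, against the preset 0.01. Otherwise the cause of these differences was not tested.

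Reversals were of values that passed in neither setting. Without the high-step pairs the score change was 0.044 for direct TGF-beta targets, 0.046 for cytotoxic genes, 0.114 for neutrophils, -0.053 for mature colonocytes, -0.016 for goblet cells, 0.013 for Wnt and stem cell genes, 0.125 for immediate early genes and -0.035 for CMS3 genes, and MNDA was at 0.008, EGR3 at 0.018, HNF4A at -0.017 and MKI67 at 0.026. Given the epithelial change it was 0.079 for direct TGF-beta targets, 0.006 for the fibroblast response, 0.057 for cytotoxic genes, 0.067 for neutrophils, -0.236 for mature colonocytes, -0.092 for goblet cells, -0.00 for cell cycle genes, 0.099 for immediate early genes and -0.059 for CMS3 genes. Without the pair farthest from the median change it was 0.005 for cytotoxic genes, 0.101 for squamous epithelium, 0.091 for Wnt and stem cell genes, -0.037 for hypoxia, 0.044 for immediate early genes and 0.015 for mitochondrial mRNAs. With z-scores hypoxia was at -0.002. With the epithelial covariate BMP2 was at -0.02, ABCC9 0.003, CCL5 0.005, GBP5 0.033, AGR2 -0.009, HNF4A -0.055, TGFBR1 0.049 and COL1A1 0.132. With library weights VWF was at -0.009, S100A9 0.187, MNDA 0.114, PDK1 0.051, TGFBR1 0.017 and SMAD7 0.049. With patient as a random effect MKI67 was at 0.009.

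The relation of TGF-beta targets with cytotoxic genes was -0.263 given the epithelial change and -0.242 after quantile normalization, where regulatory T cell genes gave -0.037 and epithelial genes -0.288, no longer past the threshold. That with the interferon-gamma response was 0.327 given the epithelial change. The remaining 331 list values, 1361 gene values and 9 correlations between the days kept their direction and their side of the threshold. The exclusion for low gene detection was not run, since 0 libraries met it, and the mean filters removed no gene. Count models were not run. In high-step libraries 1 read moves the log2 value of low genes most.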

Other observations

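The relabelling tests, the runs without high-step libraries and the mean change given the epithelial change were chosen after the results were seen, as was the choice of these patterns. A second list of 52 p53 targets, written before its values were looked at, had 51 measured genes. None of them is on the first list or among the genes of smallest unadjusted p given above. Of the 51 genes, 39 had a higher mean at Day15 and 12 a lower one, and the mean score was higher in 25 of 36 patients. The median change over all 12292 tested genes was 0.0149. AEN, an exonuclease induced by p53, had a value of 0.40 ± 0.13 (SE), PLK2, a stress-induced kinase, 0.40 ± 0.17, and CCNG1, a cyclin, 0.22 ± 0.10. With limma 9 genes of this list had an unadjusted p under 0.05, and their adjusted p over all genes was 0.852. Across patients the p53 change correlated with that of immediate early genes at r = 0.387 (p = 0.0193, adjusted p = 0.116 over 6 relations) and rho = 0.459 (adjusted p = 0.0328), and r was 0.311 without the 2 farthest patients. That list was written for immediate early and handling stress genes, and whether handling of the biopsies bears on the p53 change was not tested.

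The rise of p53 targets may reflect a damage response in the tumours, which is a hypothesis found in these data and was not tested. Other explanations were weighed on the same data. Of 100 labellings of the days within patients, the real one included, 1 gave a change as large in size as 0.337. The largest other size was 0.294, of a labelling with a fall. This repeats the sign-flipping test of the p53 score with fewer relabellings. It does not allow for the choice of this list after the scores were seen, so it adds no evidence on the cause. More epithelium and the high-step libraries are argued against as the whole cause of the change in the first list. Its change was 0.353 (95% interval 0.179 to 0.527) at no change of the epithelial score and 0.355 (0.183 to 0.526) without the high-step pairs. The second list, at 0.113 (0.029 to 0.197, permutation p = 0.01), argues against a few members alone. For the second list no value is given at no epithelial change or without the high-step pairs, so neither cause is weighed for it. Fewer cycling cells stay open, with r = -0.046 (-0.369 to 0.287) between the p53 and cell cycle changes. The cell cycle score itself had a mean change of 0.059 (95% interval -0.335 to 0.452), which shows no fall but does not exclude one. Also open and untested are galunisertib itself, chemoradiation if it had begun before the second biopsy (the labels name both treatments without dates) and the first biopsy's injury, since there was no untreated arm.

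The wide spread of matrix change between patients could come from the share of stroma in each biopsy. The matrix and epithelial changes gave r = -0.293 (-0.567 to 0.039, permutation p = 0.0827) and rho = -0.48 (p = 0.00337), which leaves this open. A depth difference within a pair also stays open, with r = 0.133 (-0.204 to 0.443, permutation p = 0.444) and rho = 0.004 (p = 0.984) between the sizes of both, and r = 0.034 without the 2 farthest patients. No biological explanation was tested.

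Relabelling the days says nothing about chance for the count of genes past the threshold, since that count was 0. With 0 genes past the threshold in limma (625 at an unadjusted p under 0.05, 718 by the signed-rank test), all 100 of 100 labellings of the days within patients gave as many by construction. The highest other gave 285 genes past the threshold, and whether a structure of the samples lies behind that labelling was not tested. At an unadjusted p under 0.05 in limma, the other labellings gave from 71 to 3017 genes. The real count of 625 lay inside that range, so it did not stand out from relabelled days.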
